A study of Mus musculus with 2 samples.

How the data were processed

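MicroRNA sequencing of embryonic day 12.5 mouse midbrain was analysed from 2 libraries, which the labels describe as biological replicates 1 and 2 of 1 tissue. Per the labels, replicate 1 was a pool of 120 embryos and replicate 2 a pool of 88 embryos of strain B6NCrl, both sexes mixed, and the RNA size range was below 30 nucleotides. The libraries formed 1 group, so no conditions were compared.

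The deposited files hold raw counts, that is whole numbers of reads per microRNA gene, with no normalization. Per the deposited read-me files, the counts were derived from alignments to the mouse assembly mm10 with annotation release M4. The aligner and the counting program are not given in the sources used here. The layout, with leading rows for unmapped, multimapping, unassigned and ambiguous reads and 3 count columns, is that of per-gene counts from the STAR aligner. The 3 columns hold reads on either strand, on the gene's own strand and on the opposite strand. The own-strand column was used, because it held 97.6% of the reads assigned on either strand in replicate 1 and 97.5% in replicate 2. Reads that aligned to several places stand in a row of their own and were assigned to no gene, so a microRNA encoded by identical gene copies can be undercounted.

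Replicate 1 held 10743770 reads, of which 17.9% were unmapped, 33.4% multimapping and 5.60% aligned elsewhere than on the own strand of an annotated gene, and 4629302 (43.1%) were assigned to a gene on its own strand. Replicate 2 held 6717347 reads, with 19.8% unmapped, 33.4% multimapping, 5.04% elsewhere than on a gene's own strand and 2805487 (41.8%) assigned. The 5.60% and 5.04% include the 113751 and 71032 reads on the opposite strand of an annotated gene. The rows that name no gene stayed out of library sizes and tests and took 56.9% of reads in replicate 1 and 58.2% in replicate 2. A floor of 3 counts corresponded to 0.648 CPM (counts per 1000000 assigned counts) in replicate 1 and 1.07 CPM in replicate 2. Intervals are 95% Wilson intervals, and intervals, floors and counting errors cover counting error only, since reads amplified by PCR are not independent molecules.

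The table lists 1973 genes by Ensembl identifier. Symbols, positions and hairpin sequences came from GENCODE release M21 on GRCm38, the same assembly as mm10, in which 1894 identifiers were found. The other 79 identifiers held 2 reads in replicate 1 and 6 in replicate 2. A microRNA gene was called exonic if it overlapped an exon of any transcript of the named host gene on the same strand, and intronic if it lay within the host but not in an exon. A hairpin was said to share sequence when 20 consecutive bases, on either strand, also occurred in an annotated microRNA hairpin at another place in the genome. This sharing rule at first counted overlapping genes at 1 locus as copies and was changed before any result of the test that used it was seen. Positions of microRNAs on the opposite strand were taken from a RefSeq gene table on GRCm38.p6.

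CPM values were own-strand counts divided by the library's total of assigned own-strand counts. A gene was quantified with at least 10 counts in both libraries. The libraries were compared gene by gene with a two-sided Fisher's exact test of the gene's count against all other assigned counts, with Benjamini-Hochberg adjustment at 0.05. That test sets the difference between these 2 libraries against counting noise and does not compare conditions. Log2 ratios are replicate 2 over replicate 1, with a counting error (SE) from the counts. Pearson and Spearman correlations used log2(CPM + 1). The biological coefficient of variation, the spread between replicates beyond counting noise, was taken from the common dispersion of edgeR 4.0.16 with TMM factors, and its error from 100 bootstrap draws of genes. For 20 lists of microRNAs, summed CPM was computed. For the 16 lists with at least 3 quantified genes, the median log2 ratio was placed among 10000 random lists of the same size matched on deciles of mean CPM. Neighbouring genes on the same strand within 10 kb were compared with random pairs by a two-sided permutation test with 100000 resamples.

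The design, the lists, the rule for named genes and the alternatives, except 3 versions of the multi-copy comparison added after its first result was seen, were set before the data were examined. The rule names the 20 genes with the highest mean CPM, up to 4 most abundant members of each list, and the 5 genes with the largest log2 ratio in each direction among those with adjusted p under 0.05 and at least 100 counts in either library. Any other gene is named as chosen after its values were seen. The lists cover brain-enriched microRNAs, let-7, the Mir99, Mir100 and Mir125 families, the Mir17hg cluster with its paralogs, the Dlk1-Dio3 clusters, families used by most cell types, the Hox clusters, erythroid, leukocyte, endothelial, mesenchymal, muscle, liver, epithelial, sensory-organ, choroid plexus and ciliated cell, endocrine and pluripotency microRNAs, the Sfmbt2 intron cluster and the X-linked testis cluster. No gene was in more than 1 list.

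The exact test, the dispersion, the list percentiles, the neighbour test and the stratified permutation test were tested on simulated data. In counts drawn for 379 genes from the means and library sizes of these libraries, the exact test called 1.60% of unchanged genes, 67.3% of genes changed 1.25-fold, 79.5% of those changed 1.5-fold and all of those changed 2-fold or 4-fold. These simulated counts held counting noise alone, without further spread between replicates. The 1.60% is therefore no rate of false calls for separate pools of embryos. A simulated biological coefficient of variation of 0.2 over 380 genes was recovered as 0.206. Of 200 lists of 8 genes drawn at random from the 380, 5% fell outside the central 95%, and of 50 lists shifted by 0.5 on the log2 scale, 90% lay above the upper bound. Of 100 permutation tests of neighbours on unlinked values, 5% gave p under 0.05, and 1 such permutation test on similar neighbours gave p = 0.002. The stratified permutation test gave p = 0.343 without a difference and 0.001 with a difference of 2, in 1 simulation of 60 genes each. Alternatives were counts on either strand, other count minimums, TMM or DESeq2 1.42.0 scaling, a pseudocount of 10, the deeper library thinned to the total of the shallower, the most abundant gene left out of the total, copies of a microRNA summed, other neighbour distances, and each replicate left out. Python 3.11.15 with SciPy 1.17.1, pandas 2.3.3 and NumPy 2.4.6 and R 4.3.3 were used.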

Results

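MicroRNA abundance was measured in the midbrain of mouse embryos at embryonic day 12.5, in 2 libraries of small RNA from separate pools of embryos. The series describes the microRNA content of this tissue, with no treatment or second tissue, so the comparisons are between microRNAs and between the 2 replicates. Replicate 1 held 4629302 counts assigned to microRNA genes and replicate 2 held 2805487. At least 1 count was found for 746 genes in either library and 643 in both. With at least 10 counts in both libraries, 380 genes were quantified, and they held 99.96% and 99.97% of the assigned counts. A mean of 1000 CPM or more was reached by 98 genes, and 22 reached 10000 CPM.

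Reads that aligned to several places, 33.4% of all reads in each replicate, were assigned to no gene and stay out of the following shares. Among the assigned own-strand reads, Mir99a was the most abundant microRNA gene in the E12.5 midbrain, with 14.3% ± 0.13 of counts (SD, n = 2). Its share was 14.4% in replicate 1 (95% Wilson interval 14.36 to 14.42%) and 14.2% in replicate 2 (14.17 to 14.25%). Mir335, which lies in an intron of the imprinted gene Mest, followed with 6.27% ± 0.09 (SD, n = 2). Mir17, of the Mir17hg cluster (commonly called the miR-17 cluster) known from dividing cells, took 5.92% ± 0.86, and Mir100, of the same family as Mir99a, took 4.48% ± 0.12. The 10 most abundant genes together held 47.8% ± 0.03 of counts and the 20 most abundant 63.4% ± 0.42 (SD, n = 2).

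The other genes among the first 10 were Mir130a with 3.61% ± 0.20 of counts, Mir99b with 3.06% ± 0.19, Mir30e with 2.97% ± 0.15, Mir126a with 2.48% ± 0.20, Mir92b with 2.37% ± 0.59 and Mir26b with 2.35% ± 0.17. The next 10 were Mir20a, Mir93, Mirlet7g, Mir30a, Mir342, Mir149, Mir106b, Mir322, Mir181c and Mirlet7i, from 2.21% ± 0.44 for Mir20a down to 1.13% ± 0.19 for Mirlet7i. On mm10, Mir99a (ENSMUSG00000065530.1) lies on chromosome 16 from 77598936 to 77599000 in an intron of the non-coding gene Mir99ahg. Mir335 (ENSMUSG00000065501.1) lies on chromosome 6 from 30741299 to 30741396, and Mir17 (ENSMUSG00000065508.1) on chromosome 14 from 115043671 to 115043754 in an exon of the non-coding gene Mir17hg. Mir100 lies on chromosome 9 from 41531425 to 41531504 in an intron of the non-coding gene 3110039I08Rik. Mir126a, a microRNA of endothelial cells, lies in Egfl7 on chromosome 2 from 26591357 to 26591429. Of the 20 genes, 11 lay in introns of a gene on the same strand, 5 overlapped exons and 4 were intergenic. None of the 20 hairpins shared 20 bases with another annotated microRNA gene, while 83 of the 380 quantified genes did. MicroRNAs with several gene copies may therefore rank too low here.

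**Figure D1:**
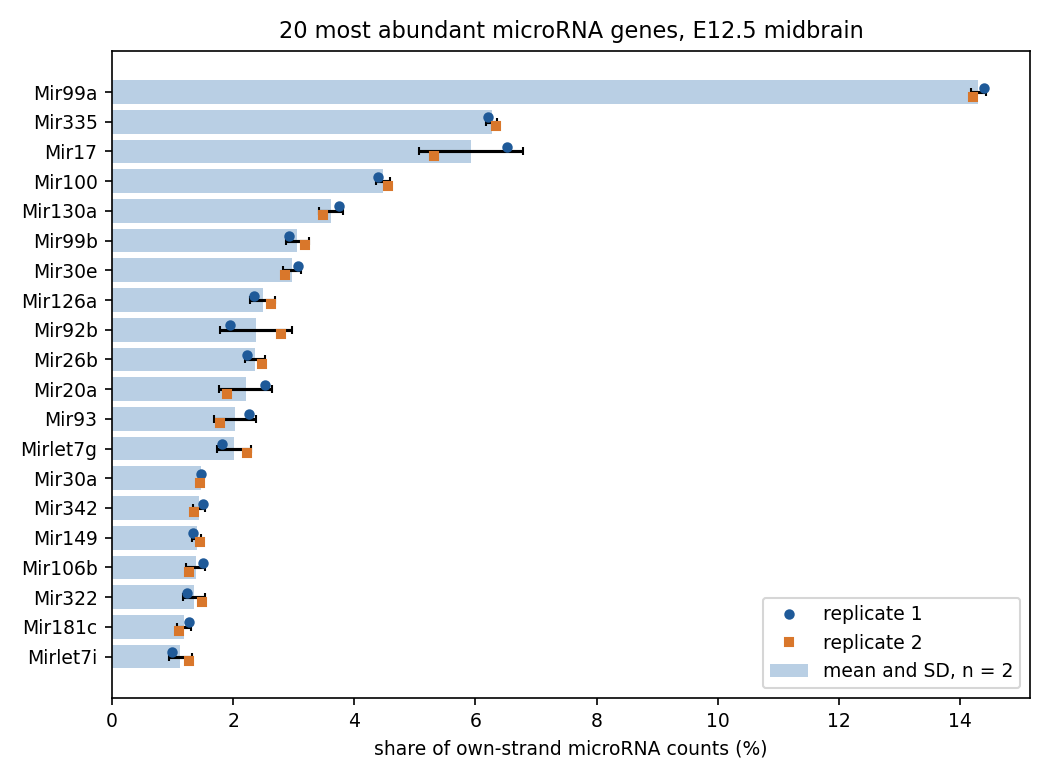
Share of own-strand microRNA counts, in percent, for the 20 most abundant genes. Reads that aligned to several places are not counted. Bars are means with SD over n = 2 libraries and the points are the 2 libraries. Mir99a held 14.3% of counts, and Mir335, the second, held 6.27%.

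By fixed list and among assigned own-strand reads, the Mir99, Mir100 and Mir125 families were the most abundant, with 227400 ± 3120 CPM (SD, n = 2) over 6 detected genes. They were led by Mir99a (143031 ± 1263 CPM), Mir100 (44753 ± 1180 CPM), Mir99b (30555 ± 1920 CPM) and Mir125a (5412 ± 1113 CPM). That first place rests on Mir99a: with it left out of the list and the total, the list gave 98446 CPM, below the other 2 largest lists at 200897 CPM and 166032 CPM. Families used by most cell types summed to 172158 ± 6267 CPM over the 32 of 34 members detected in both libraries, led by Mir130a, Mir30e, Mir26b and Mir30a. The Mir17hg cluster and its paralogs reached 142268 ± 21410 CPM over 15 genes, with Mir17 (59214 ± 8579 CPM), Mir20a (22080 ± 4385 CPM), Mir93 (20240 ± 3454 CPM) and Mir106b (13792 ± 1614 CPM) the highest. The imprinted Dlk1-Dio3 clusters gave 65177 ± 5579 CPM over 45 of 51 members, led by Mir487b (11090 ± 719 CPM), Mir369, Mir127 and Mir411. Reads over Mir409, Mir376a, Mir380 and Mir299a lay on the opposite strand of other annotated genes and are not in this sum. Those over Mir409 would stand at 8302 CPM, above Mir369. The let-7 family, known to rise as progenitors differentiate, gave 35978 ± 5947 CPM over 10 genes, led by Mirlet7g (20205 ± 2811 CPM), Mirlet7i (11259 ± 1932 CPM), Mirlet7d (2051 ± 735 CPM) and Mir98 (1371 ± 305 CPM). The 10 genes are those found by symbol and do not include Mirlet7e, whose place had opposite-strand reads at 4262 CPM, above Mirlet7d. Of these 10 genes, 5 shared 20 bases with another annotated hairpin, as did 16 of the 34 members of the families used by most cell types, so their counts omit any reads that aligned to several copies. The median of the 5 let-7 genes that share sequence was 102.9 CPM, against 2051 CPM for the other 5.

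Brain-enriched microRNAs summed to 14435 ± 131 CPM (SD, n = 2), with counts in both libraries for all 25 members found by symbol. Mir137 was highest at 3894 ± 467.3 CPM, followed by Mir153 at 3399 ± 159 CPM, Mir219a-2 at 3042 ± 971 CPM and Mir219a-1 at 1192.6 ± 144.6 CPM. Of these 25 genes, 17 shared 20 bases with another annotated hairpin, Mir219a-1 and Mir219a-2 included, so their counts omit any reads that aligned to several copies. The Sfmbt2 intron cluster, in which 67 of 69 genes shared such sequence, gave 6007 ± 8.71 CPM. In it, 19 genes had at least 1 count in both libraries and 10 were quantified, led by Mir467d, Mir467c, Mir467e and Mir669o.

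MicroRNAs of other regions and cell types ranged widely in level. In the mesenchymal, pluripotency, leukocyte, Hox cluster, muscle and testis lists, some members share 20 bases with another annotated hairpin. Their counts omit any reads that aligned to several copies. Endothelial Mir126a stood at 24839 ± 1986 CPM (SD, n = 2) and the mesenchymal list at 19649 ± 5575 CPM over 7 of 8 members, led by Mir143 (9818 ± 2169 CPM), Mir140 (4858 ± 1087 CPM), Mir214 (4349 ± 2176 CPM) and Mir199b (434.3 ± 121.8 CPM). The sensory-organ cluster of Mir182, Mir183 and Mir96 gave 4301 ± 570 CPM. The pluripotency list gave 3258 ± 204.4 CPM over 12 genes, led by Mir302a, Mir302d, Mir302b and Mir302c, and the epithelial list 3157 ± 555 CPM over 7, led by Mir203, Mir205, Mir429 and Mir200c. The choroid plexus and ciliated cell list gave 2356 ± 1290 CPM over 7 genes, led by Mir449a, Mir34c, Mir204 and Mir34b. Leukocyte microRNAs gave 688 ± 114 CPM over 4 of 5 members, Mir223, Mir155, Mir146 and Mir150, and with reads of either strand counted the list rose to 1077 CPM. Endocrine Mir375 gave 600 ± 224 CPM, the erythroid list of Mir451a, Mir144 and Mir486 gave 342 ± 100 CPM and the Hox cluster list of 6 members, 5 of them detected in both libraries, gave 322 ± 136.8 CPM, led by Mir10a, Mir10b, Mir196b and Mir615. Muscle microRNAs stood at 63.3 ± 5.78 CPM over 5 of 10 members, with Mir208b, Mir206, Mir208a and Mir499 the highest. Of the 10, 5 share sequence, among them Mir1a-1, Mir133a-1 and Mir133a-2, named after their values were seen, which had no assigned reads. Their absence from the counts therefore does not show that they were absent from the tissue. Liver Mir122 stood at 39.1 ± 43.0 CPM, and the X-linked testis cluster at 3.54 ± 1.04 CPM over 5 of 20 members, with Mir741, Mir201, Mir463 and Mir881 the highest. The testis sum rests on only 13 reads in replicate 1 and 12 in replicate 2, and none of its genes was quantified.

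The replicates were then compared with each other. The gene with the largest difference was liver microRNA Mir122 on chromosome 18 from 65248861 to 65248926, in an exon of the non-coding gene AC157910.3, with 8.64 CPM in replicate 1, from 40 counts, and 69.5 CPM in replicate 2, 8.04-fold higher in replicate 2. On the lower side, Mir449a, in an intron of Cdc20b on chromosome 13 from 113037534 to 113037624, was 3.68-fold higher in replicate 1 (1492 CPM against 406 CPM, log2 ratio -1.88 ± 0.05, counting SE). Mir204, in an intron of Trpm3 on chromosome 19 from 22750605 to 22750672, was 3.48-fold higher in replicate 1 (log2 ratio -1.80 ± 0.06). The adjacent Htr2c intronic genes on the X chromosome followed, with log2 ratios of -1.76 ± 0.09 for Mir1298 (147064905 to 147065002), -1.43 ± 0.21 for Mir448 (147158210 to 147158321) and -1.38 ± 0.31 for Mir1264 (147010601 to 147010686). Higher in replicate 2 were Mir483, in an intron of Igf2 (log2 ratio 1.12 ± 0.05), Mir214, in an exon of the antisense gene Dnm3os (1.07 ± 0.02), Mir10b of the Hoxd cluster (1.02 ± 0.11) and Mir146 (1.01 ± 0.14).

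Across the 380 quantified genes, Pearson's r of log2(CPM + 1) was 0.992 and Spearman's rho 0.990, across genes, which are not independent replicates. By the exact test with Benjamini-Hochberg adjustment, 54.2% of these genes differed between the libraries, 50% of those higher in replicate 2 with plain totals and 44.3% with DESeq2 size factors, and 53 genes by at least 1.5-fold, 31 higher in replicate 2 and 22 in replicate 1. At an unadjusted p under 0.05, 217 genes differed. Of the 20 most abundant genes, 19 differed and none by 1.5-fold, with log2 ratios from -0.41 for Mir20a to 0.52 for Mir92b. The log2 ratio lay within 2-fold for 365 genes and beyond it for 15. The biological coefficient of variation was 20.4% ± 1.40 (bootstrap SE over genes). A chi-square of 61271, or 162 per degree of freedom, over the quantified genes showed that the files were not the same library deposited again.

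**Figure D2:**
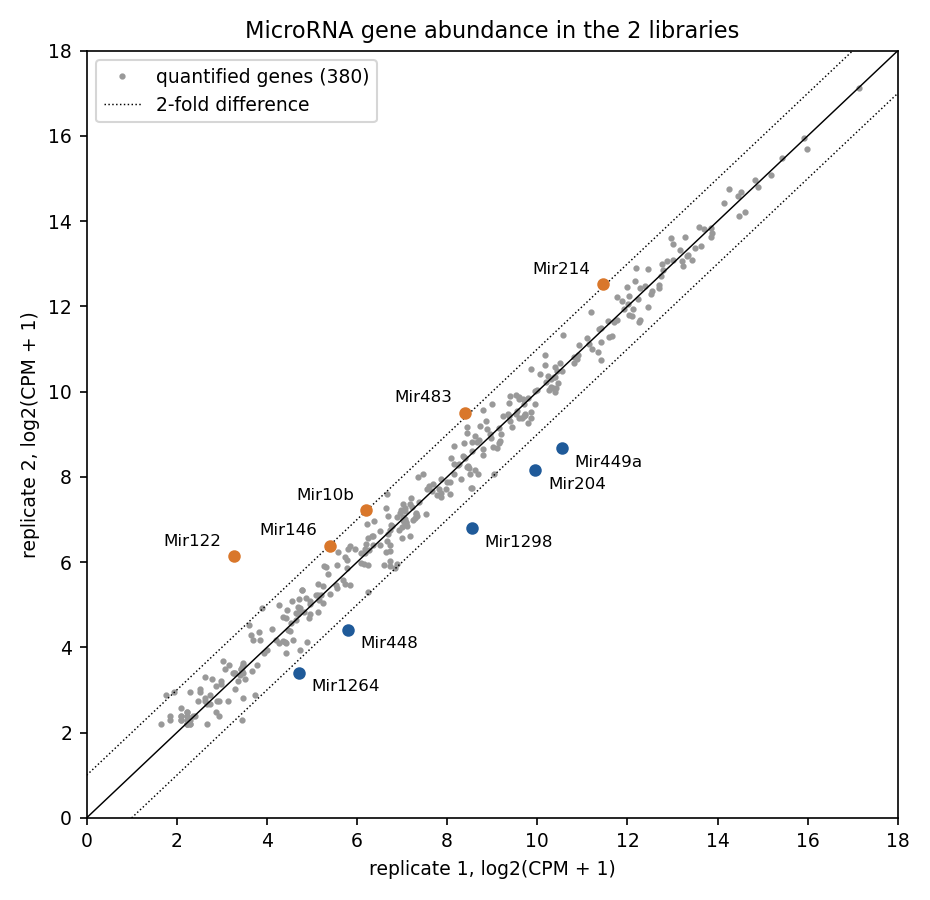
Abundance of the 380 quantified genes in replicate 1 (x axis) and replicate 2 (y axis), both as log2(CPM + 1). The solid line marks equal values and the dotted lines a 2-fold difference, and the 5 genes with the largest called ratios in each direction are named. Mir449a, Mir204 and the Htr2c intronic genes lie below the lower dotted line, and Mir122 lies farthest above the upper one.

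By list, let-7 genes were higher in replicate 2, with all 10 called and a median log2 ratio of 0.36, at percentile 99.5 of random lists matched on abundance. Mirlet7g had a log2 ratio of 0.28 ± 0.01 (counting SE), Mirlet7i of 0.35 ± 0.01 and Mirlet7d of 0.75 ± 0.02. Most genes in the list of the Mir17hg cluster and its paralogs were lower in replicate 2. Of 15 genes, 10 were called lower, 2 called higher and 3 not called, with a median of -0.26 at percentile 0.275. Mir17 had a log2 ratio of -0.30 ± 0.005, Mir20a of -0.41 ± 0.01, and Mir92-1 (0.07 ± 0.01) and Mir19a (0.23 ± 0.09), named after their values were seen, were the called exceptions. The 3 genes not called, also named afterwards, were Mir92-2 (-0.02 ± 0.04), Mir19b-1 (0.13 ± 0.18) and Mir19b-2 (0.09 ± 0.34). No Mir19 or Mir92 gene of the list was thus called lower, and the list did not move as a unit. Of the 44 quantified Dlk1-Dio3 genes, 28 were called lower in replicate 2, 6 higher and 10 not called, with a median of -0.21 at percentile 0.03.

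Several lists of other regions and cell types were higher in replicate 2. All 4 quantified Hox cluster genes were called higher, with a median of 0.81 at percentile 99.9, and Mir10a had a log2 ratio of 0.93 ± 0.09. Of the 7 epithelial genes, 6 were called higher and 1 was not called (median 0.60, percentile 99.9), with Mir429 at 0.74 ± 0.05 and Mir200c at 0.66 ± 0.08. Of the 7 quantified mesenchymal genes, 6 were called higher and 1 was not called (median 0.46, percentile 99.3), with Mir143 at 0.45 ± 0.01. Of the 4 quantified leukocyte genes, Mir223, Mir146 and Mir150 were called higher and Mir155 lower (median 0.66, percentile 99.7). Counts on the opposite strand, which include reads over Mir142, Mirlet7e and 4 Dlk1-Dio3 microRNAs, were not part of these lists.

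Other lists had medians inside the central 95% of random lists. Brain-enriched genes were mixed, with 5 of 23 called higher in replicate 2, 9 lower and 9 not called, and a median of -0.13 at percentile 8.81. Mir219a-2 had a log2 ratio of 0.66 ± 0.02 and Mir137 of -0.25 ± 0.02. In the choroid plexus and ciliated cell list, Mir449a and Mir204 were called lower and 3 genes were not called, Mir34c at -0.05 ± 0.04 among them. Its median was -0.05 at percentile 27.9, while its mean was -0.70 and its summed CPM moved by -1.18 on the log2 scale, from 3268 to 1444 CPM. The erythroid median was 0.20 at percentile 85.3 but the log2 ratio of its summed CPM was -0.61, because Mir451a, its most abundant member, had -0.81 ± 0.07 while Mir486 had 1.08 ± 0.24.

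Among the remaining lists with at least 3 quantified genes, the medians were 0.45 for the sensory-organ cluster (percentile 94.4), 0.34 for muscle (87.2), with none of its 5 genes called, 0.09 for the Mir99, Mir100 and Mir125 families (75.9), 0.05 for pluripotency (56.5), 0.04 for the Sfmbt2 cluster (51.3) and -0.07 for families used by most cell types (16.6). The numbers of genes called higher and lower in replicate 2 were 2 and 1 for the sensory-organ cluster, 4 and 1 for the Mir99, Mir100 and Mir125 families, 1 and 0 for pluripotency, 2 and 1 for the Sfmbt2 cluster and 7 and 14 for the broad families. Single-gene lists were called higher in replicate 2 for Mir126a (log2 ratio 0.16 ± 0.01), Mir375 (0.78 ± 0.04) and Mir122. Adjusted over the list alone, 35 Dlk1-Dio3 genes and 7 epithelial genes were called in either direction, against 34 and 6 over all genes tested, and no other list's count differed. In all, 7 of 16 lists lay outside the central 95%. The random lists take genes as independent, while neighbouring genes had more similar ratios than random pairs. Lists drawn from genomic clusters, such as the Dlk1-Dio3 list, can therefore fall outside more often than the random lists imply. These percentiles describe 2 libraries and test no condition.

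**Figure D3:**
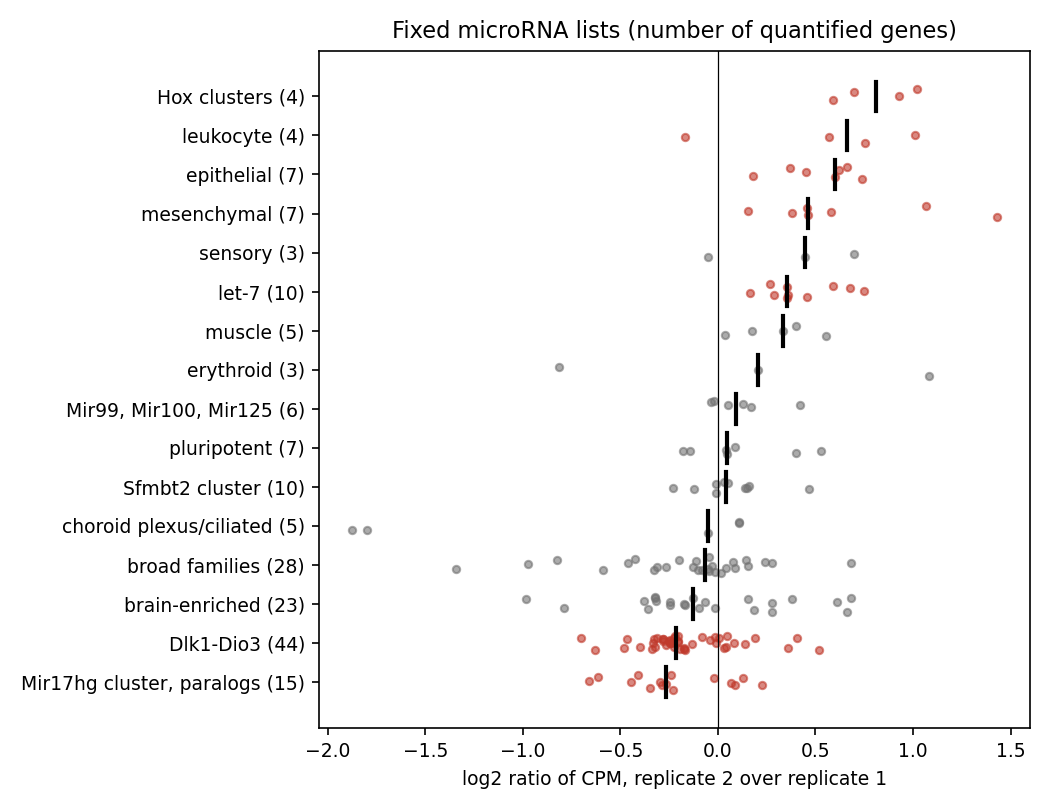
Log2 ratio of CPM, replicate 2 over replicate 1 (x axis), for the quantified genes of 16 fixed lists, with the number of genes in brackets. Points are genes and black bars medians, and red marks the 7 lists whose median lay outside the central 95% of matched random lists. The Hox list has the highest median, 0.81, and the Mir17hg cluster list the lowest, -0.26.

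Neighbouring microRNA genes, pooled over all clusters, had more similar ratios between the libraries than random pairs, and no cluster was tested by itself. Over 110 pairs of same-strand neighbours within 10 kb, the mean absolute difference in log2 ratio was 0.33, against 0.48 for random pairs (two-sided permutation p = 0.00014, 100000 resamples). The mean absolute difference in log2(CPM + 1) was 3.46, against 3.98 for random pairs (two-sided permutation p = 0.0496). Pairs that share a gene are not independent. The random pairs came from all quantified genes, not only from those with a neighbour. The p-values therefore do not separate similar neighbours from clustered genes that vary less between the libraries, for example through higher counts.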

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

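Reads outside the own-strand counts were examined because their number was above what a count of 0 allows, and the multi-copy comparison was run in 4 versions, 3 of them chosen only after the first result was seen.

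Reads on the strand opposite to an annotated microRNA gene numbered 113751 in replicate 1 and 71032 in replicate 2. The 9 genes with at least 1000 such reads in both libraries held 99.4% and 99.5% of them, and at each place the RefSeq table lists another microRNA. The largest, Gm24321 on chromosome 12 from 109743158 to 109743237, lies over Mir409 and had 41529 opposite-strand reads in replicate 1 and 21416 in replicate 2. In replicate 1, Gm25927 over Mirlet7e had 17136 such reads, Gm24083 over Mir191 had 13128, Gm25301 over Mir378a had 12673, Gm25252 over Mir376a had 12338 and Gm25750 over Mir380 had 6126. Mir299b over Mir299a had 5659, Mir497b over Mir497 had 2869 and Mir142b over Mir142 had 1646. Relative to the own-strand total, Gm24321 would stand at 8302 ± 946 CPM (SD, n = 2), which would rank 31 among the genes. The RefSeq table used gives no strand, so the strand of the listed microRNA was not checked.

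Reads that aligned to several places were also outside the gene counts. They numbered 3589504 in replicate 1 and 2242911 in replicate 2, which is 40.7% and 41.6% of the aligned reads. Some brain microRNAs with several gene copies, named after their values were seen, had few assigned reads. The 2 Mir9 genes found by symbol, Mir9-2 and Mir9-3, had 1485 reads together in replicate 1 and 699 in replicate 2. The highest of the 3 Mir124a genes, Mir124a-2, stood at 14.6 ± 0.46 CPM (SD, n = 2). All 5 hairpins shared 20 bases with another annotated hairpin, but so did Mir219a-2, which stood at 3042 ± 971 CPM.

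A candidate explanation for these low counts is that reads of identical copies were set aside as multimapping. In the version set in advance, genes that share sequence were compared with other genes of the same list over 13 lists, and the difference in median log2(CPM + 1) was -1.59, with a two-sided stratified permutation p of 0.174 (20000 resamples), which does not decide. The same permutation test in the 3 later versions gave -2.86 without the Sfmbt2 list (p = 5e-05, the smallest these resamples give), -4.30 in the let-7 list alone (p = 0.0485) and -0.74 in the brain-enriched list alone (p = 0.780). The version set in advance and the brain-enriched list alone both missed the threshold, which does not speak against reads set aside. The counting leaves out any read that aligns to several copies, but how many such reads belong to each gene is not known. The sharing rule uses whole hairpins and does not show whether the shared bases lie in the sequenced arm. The level of Mir219a-2 therefore does not speak against reads set aside. The few assigned reads of the Mir9 and Mir124a genes do not show that these microRNAs were scarce in the tissue. How far low expression of these genes at this age and how far reads set aside lowered the counts cannot be told apart here. No biological explanation was tested.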

How the results depend on the processing

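Of 42 recomputed values for the main results other than list medians, 37 stayed within the limit for their kind. The limit was the same direction and side of the threshold for a test, and 1.5 times for a count. It was the spread between replicates for a share. For the correlation and the biological coefficient of variation it was the bootstrap error over genes. The number of genes rose from 380 to 643 with at least 1 count in place of 10 in both libraries, since fewer genes were filtered out. The share of the 10 most abundant genes was 46.6% with either strand counted, since opposite-strand reads enlarge the total, and ranged from 47.8% to 48.4% when a replicate was left out and the 10 were chosen anew. For the comparison of multi-copy with other genes, the versions chosen after seeing the data gave -2.86 without the Sfmbt2 list and -4.30 in the let-7 list alone, both past the threshold that the version set in advance had missed, and the cause was not tested. Across the alternatives, the number of genes that differed between the libraries stayed within 1.5 times of the reported one, and 40 to 58 genes differed by at least 1.5-fold. DESeq2 scaling moved every log2 ratio by -0.04 and TMM by -0.01, and no list median changed sign; a common factor cannot move a list's percentile, so that was not tested. The share of 1.5-fold differences higher in replicate 2 was 58.5% with plain totals and 51.0% with DESeq2, and of all differences 50% and 44.3%. At least 19 of the 20 most abundant genes stayed among the first 20 under each of the 6 alternatives for abundance. With Mir99a left out 19 was the most possible, and TMM and DESeq2 scale all genes of a library alike, so these settings hardly test the ranking. With Mir99a left out of the total, CPM values of other genes rose up to 1.17 times and the list of the Mir99, Mir100 and Mir125 families fell to 98446 CPM, 0.43 times its level, since Mir99a is its main member. Results that need both libraries have no value with a replicate left out, and Mir122 rests on replicate 2, at 69.5 CPM against 8.64 CPM. No paired analysis was possible because the libraries form 1 group. Below 0.648 CPM in replicate 1 and 1.07 CPM in replicate 2, depth sets the limit of detection.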

Other observations

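MicroRNAs outside the fixed lists and the 20 most abundant genes were also examined, and the genes in the next sentences were chosen after their values were seen. Mir23b, in an intron of 2010111I01Rik, stood at 10235 ± 3108 CPM (SD, n = 2) and Mir23a at 6164 ± 2077 CPM, and both were higher in replicate 2, with log2 ratios of 0.63 ± 0.01 and 0.70 ± 0.01 (counting SE). Their hairpins share 20 bases with another annotated hairpin. Mir135b stood at 9027 ± 696 CPM, Mir21a, in an exon of Vmp1, at 8003 ± 718 CPM and Mir708, in an intron of Tenm4, at 2773 ± 409.3 CPM. The neighbouring Mir296 and Mir298 on chromosome 2 stood at 6796 ± 50.6 CPM and 5249 ± 402 CPM.

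Members of the same cluster differed widely in abundance. In the Mir17hg cluster, Mir17 stood at 59214 ± 8579 CPM (SD, n = 2), Mir20a at 22080 ± 4385 CPM, Mir18 at 8814 ± 1237 CPM and Mir19a at 143.2 ± 15.8 CPM, although Mir19a shares no 20 bases with another annotated hairpin. Mir143 stood at 9818 ± 2169 CPM and its neighbour Mir145a at 139.8 ± 10.5 CPM. Mir302a stood at 1184 ± 24.3 CPM and Mir367, of the same cluster, at 1.22 ± 0.72 CPM. The differences were not tested further.

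The tests of the choroid plexus pattern were all chosen after the result was seen. Mir449a and Mir204, microRNAs known from choroid plexus and picked here for their low ratios, were lower in replicate 2, with log2 ratios of -1.88 ± 0.05 and -1.80 ± 0.06 (counting SE). Library scaling, which moves every gene alike, was excluded, since the median log2 ratio of all quantified genes was 0.04 ± 0.02 (bootstrap SE). Ciliated cells as the source would lower Mir34b and Mir34c as well, if both come mainly from those cells. Their median log2 ratio was 0.027 ± 0.11, but their source was not tested, so ciliated cells stay open. Mir449c and Mir449b, named after their values were seen, had 22 and 14 counts in replicate 1 and 2 counts each in replicate 2. More choroid plexus in the tissue of replicate 1 may account for the low ratios of Mir449a and Mir204. The fixed list does not separate choroid plexus from ciliated cells, so the flat median of Mir34b and Mir34c bears on both explanations. The 3 quantified microRNAs in introns of Htr2c, a gene choroid plexus uses strongly, had a median of -1.43, at percentile 0.035 of random lists. Those Htr2c genes had already been seen among the lowest ratios and lie in 1 host gene, so more choroid plexus stays open as a hypothesis. A difference between the pools in embryo stage or in dissection was not tested.

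The medians of the let-7 list and of the list of the Mir17hg cluster and its paralogs shifted in opposite directions. For these shifts, the GC test was set before its result was seen. The rule that a flat trend decides nothing and the test on other cell types came after that result. The gap between the medians of these lists was 0.62 on the log2 scale, with let-7 higher in replicate 2. A correction for hairpin GC content left 100.6% of that gap, but the lists had like median GC (46.3% and 45.8%) and the trend was nearly flat, so the correction had nothing to remove and GC content, which was not tested for the sequenced arm, stays open. Less neural tissue in replicate 2 as the only cause would raise lists of all other regions and cell types alike. Of 11 such lists 9 had a higher summed CPM, with log2 ratios such as 0.16 ± 0.01 for endothelial Mir126a and 0.89 ± 0.06 for the Hox list. A lower one was found for 2, -1.18 ± 0.03 for the choroid plexus and ciliated cell list and -0.61 ± 0.06 for the erythroid list, the latter through Mir451a alone. The summed CPM of the brain-enriched list had a log2 ratio of -0.02. That sum includes the rise of Mir219a-2 (0.66 ± 0.02), while 9 of its 23 quantified genes were called lower and 5 higher. Their median was -0.13, so the sum alone does not show an unchanged brain-enriched content. The lowest value among the 11 lists belongs to the choroid plexus pattern described above, and the test was chosen after results were seen, so it does not decide. Less neural tissue as part of the cause stays open. More mesenchyme, surface tissue or caudal tissue in replicate 2, or slightly older embryos, could each give part of the shifts and stay open, as they were not tested.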
